A study of Mus musculus and Homo sapiens with 20 samples.

How the data were processed

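The series holds 20 samples, of which 12 are RNA-seq libraries of cultured melanoma lines, with 3 replicates in each of 4 groups. The other 8, ChIP for the histone mark H3K27ac and its inputs in B16-F10, were not analysed here. Groups were taken from the sample titles and each column of a count table was matched to a sample by its name. Replicate numbers were not used to pair samples in the main comparisons.

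The values in both count tables are whole-number read counts per gene symbol, which the authors made by aligning reads with STAR 2.7.10b and counting them with featureCounts of Subread 2.0.1, on mm10 for B16-F10 and hg38 for A375, per the submitters' processing notes. FastQC, StringTie, Bowtie2 2.4.3, Picard 2.26.5 and deepTools 2.0 are named there too. The annotation release, the strand setting and the handling of read mates are not given in the sources used here. The tables held 21899 genes for B16-F10 and 19952 for A375, with the exon coordinates and the summed exon length of each gene. The A375 libraries also had a transcript assembly each, whose values are TPM made by the authors with StringTie 2.2.1 from HISAT2 alignments in stranded mode without a reference annotation, per the file headers. The aligner of these assemblies thus differs from that of the counts. Transcript names in them belong to a single library, so tests of annotated transcripts and of isoform shares were not run. TPM was summed per gene of the count table with the longest exon overlap on either strand, found with bedtools 2.31.1, for an alternative. A genome sequence was not used here, so GC content was not examined.

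The total of counts was 16103397 to 18259830 per library in B16-F10 and 15495271 to 18441512 in A375. Genes were kept by filterByExpr of edgeR 4.0.16, scaled by TMM and tested with its robust quasi-likelihood test (glmQLFit, glmQLFTest, two-sided) in R 4.3.3, with PRMT1 loss against control in each line by itself. A gene passed at a Benjamini-Hochberg adjusted p under 0.05. CPM values use library totals multiplied by the TMM factors. The fold changes printed are the log2 coefficients of this model, and where a group held 0 to 3 counts the text gives a bound from a floor of 3 counts over the group or a ratio of counts with its exact 95% interval. The difference between the lines was tested as an interaction of line and PRMT1 loss on genes paired by symbol, with TMM factors computed within each line, and the overlap of changed genes with Fisher's exact test (two-sided).

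The main tests and 27 gene lists, 4 of them markers of other cell types, were fixed before the data were examined, as were most of the alternatives. Lists were tested on the edgeR fit's data with camera of limma 3.58.1 at a preset correlation of 0.01, with camera at an estimated correlation and with fry, and adjusted over the lists of a line. A call lost at an estimated correlation need not mean that its genes were correlated more strongly than the preset. A list needed at least 2 tested members. The tests of list differences between the lines, of chromosomes and of genes silent in sg1 were chosen after the data had been seen, as were the alternatives with sg1 replicate 3 alone, with replicates 1 and 2 summed and with chromosome medians removed and the assignment of assembled transcripts to genes. Genes were named by a rule. It takes the PRMT family, the 8 largest rises and 8 largest falls per line among genes past the threshold with at least 1 CPM in the higher group, ranges that did not overlap and a symbol that is not a code for a predicted gene. It also takes up to 4 members of each list with the largest absolute change among those past the threshold at 1 CPM or more, or, where none passed, up to 2 with the highest level, the 6 largest differences between the lines with at least 1 CPM in both, and the 8 genes changed in the same direction in both lines with the largest smaller change. The text names a part of the members so found, mostly those whose calls held with any library left out. Some members are not reported here.

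Alternatives were RLE scaling, library totals only, no filter beyond 1 count, a filter of 1 CPM in 3 libraries, the replicate block, DESeq2 1.42.0, limma-voom, glmTreat against 1.5-fold, an adjusted p of 0.01, a minimum of 2-fold, and leaving out each library in turn. With a line's libraries reduced to 5, the smaller group keeps 2. Where sg1 replicate 3 alone was set against CTRL, the spread was pooled and the lone library is assumed to vary like the CTRL group. Other splits of the libraries were fitted, all 10 in each line and 100 drawn of the 200 for both lines. Library quality was compared with exact permutation tests. Chromosome medians were tested with 10000 rotations of the changes along the gene order, and windows of 20 Mb needed at least 15 genes.

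The procedure was tested on simulated data, with 10 draws and 200 changed genes each, at the depth of these libraries and the spread of each gene. Genes were drawn independently, so a departure shared by many genes, as in sg1 replicate 3, was not simulated. Far fewer genes were changed than were called in the real data. For the difference between the lines, changes were put into B16-F10 only. The rates below hold for this setting and need not hold for the real data. Changes of 1.5-fold, 2-fold and 4-fold were recovered for 43.9%, 81.7% and 94.1% of genes in B16-F10, for 75.7%, 92.1% and 99.5% in A375 and for 36.1%, 82.5% and 95.7% in the difference between the lines. The share of calls on unchanged genes was 7.39%, 5.12% and 11.3%, above the nominal 5% in the first and the last. A single draw had exceeded the limit set for the last, and 10 draws were then pooled with the limit unchanged. Figures and tables used Python 3.11.15, numpy 2.4.6 and matplotlib 3.10.9.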

Results

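The 12 RNA-seq libraries analysed here came from 2 melanoma cell lines, with 3 replicates in each of 4 groups. B16-F10, a mouse line, was measured as a control (CTRL) and after knockout of Prmt1 with the guide sg1. A375, a human line, was measured with a control hairpin (shNC) and with a hairpin against PRMT1 (shPRMT1). The RNA-seq of each line thus has a single guide or hairpin. Other effects of that reagent, or of the history of the cells that carry it, cannot be told apart from loss of PRMT1. A change said here to come with PRMT1 loss is a difference between these groups. PRMT1 is the main enzyme that places asymmetric dimethyl marks on arginine, on histones and on RNA-binding proteins. In B16-F10 the CTRL libraries held 16669290, 18259830 and 16226146 counts and the sg1 libraries 16312649, 16103397 and 17918450. In A375 the shNC libraries held 17462788, 17610515 and 18441512 counts and the shPRMT1 libraries 15495271, 17105267 and 18363667. At these depths a count of 3, the upper limit that a count of 0 allows, was 0.159 to 0.199 CPM, the usual count per library size. Intervals and floors given here cover counting error only. The labels do not say that replicates were separate cultures, so p-values measure the spread between these samples, which may be technical. An exact test of 3 against 3 libraries cannot go below a two-sided p of 0.1.

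First, the libraries of B16-F10 were compared to ask which genes changed with loss of PRMT1, with interferon genes foremost in the title of the series. Prmt1 (mm10, chromosome 7, 44975989 to 44986568) was read at 215, 226 and 199 CPM in the CTRL libraries and at 94.5, 85.5 and 80.1 CPM in the sg1 libraries. Its transcript fell from 213 ± 13.6 to 86.7 ± 7.25 CPM (SD, n = 3), a log2 change of -1.30 with a standard error of 0.0857 (edgeR adjusted p = 8.0e-05). Of 41 tested interferon-stimulated genes 33 rose and 0 fell (camera adjusted p = 1.7e-39, and adjusted p = 0.034 with an estimated correlation). Of 11604 genes tested, 3180 rose and 3067 fell, together 53.8%, and 688 rose and 861 fell by at least 2-fold. With replicates 1 and 2 summed within each group, an alternative chosen after the data had been seen, 3223 genes passed, and 1638 passed a test against a minimum change of 1.5-fold. The median absolute log2 change of the changed genes was 0.64. CPM ranges of the groups did not overlap for 6212 of the 6247 changed genes, and for 64.7% of all tested genes, where chance gives 10%.

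Other members of the PRMT family changed in both directions in B16-F10, where 3 of 8 tested members rose and 4 fell, with the same counts adjusted over the list alone. Carm1 (-0.70), a coactivator methyltransferase, Prmt7 (-0.70) and Prmt3 (-0.46) fell with Prmt1. With chromosome medians removed, a test described below, Carm1 was at -0.36 (edgeR adjusted p = 0.0026). Prmt6 (0.79) and Prmt2 (0.51) rose. Prmt9 rose by 0.30 (edgeR adjusted p = 0.033), a call that was lost without CTRL replicate 1 (0.12), CTRL replicate 2 (0.071), CTRL replicate 3 (0.075), sg1 replicate 1 (0.064) or sg1 replicate 2 (0.056), the numbers in parentheses being adjusted p, and over all alternatives these ran from 0.0040 to 1. Prmt5, the main symmetric dimethyltransferase, differed by 0.32 (edgeR adjusted p = 0.10) and by 0.49 without sg1 replicate 3 (7.9e-11, the lowest over its alternatives, the highest being 1). That fit leaves sg1 replicates 1 and 2, between which the variance was only 1.87 times that of counting alone. Prmt8 had 0 counts in all 6 libraries. The family did not move as a list (camera adjusted p = 0.37, median -0.08, and -0.15 to -0.05 with a library left out).

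Predicted genes and genes with 3 counts or fewer over the CTRL group left aside, the largest fitted rise was that of Rgs16 (mm10, chromosome 1, 153740349 to 153745468), a regulator of G protein signalling, from 1.48 ± 0.347 to 42.0 ± 15.9 CPM (SD, n = 3; log2 change 4.82). Neurl3 (4.42), a ubiquitin ligase, Rspo3 (4.32), an enhancer of Wnt signalling, Cfap70 (3.78), a cilium component, and Gbp5 (3.65), an interferon-induced GTPase, followed. Fgf7, a growth factor, rose by 3.63. Its 6 CTRL counts were all in replicate 2, and without that library, where the CTRL group is at 0, the fitted 7.66 is no bound. Stmn4, a stathmin, rose from 2 to 64 counts over the groups (ratio 32.9, 95% counting interval 8.73 to 277), and Mcmdc2 from 3 to 59 counts (ratio 20.2, 6.58 to 101).

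By fitted change the largest falls in B16-F10 were of genes left with almost no counts in any sg1 library. The ratios and bounds given here need not keep that order, and other genes, such as Ptgfrn below, had ratios above these bounds. Foxr2 (mm10, chromosome X, 153118786 to 153132861), a forkhead transcription factor, went from 66.1 ± 2.29 CPM (SD, n = 3) to 2 counts over the sg1 group (ratio of CTRL to sg1 1653, 95% counting interval 457 to 13657). Fam81a went from 870 counts to 1 (ratio 847, 152 to 33504). With the floor of 3 counts over the group, Osmr, a subunit of the oncostatin M receptor, was at least 112-fold lower, Col6a3, a collagen VI chain, at least 93.2-fold, Tex12, a meiotic gene, at least 81.8-fold, Bcl11a, a transcriptional repressor, at least 77.9-fold, Armcx1 at least 70.1-fold and Sgsm1 at least 63.0-fold lower. In all, 25 genes with a CTRL mean of at least 50 counts had at most 3 counts in every sg1 library. They lay on 13 chromosomes, and 6 of the 25 genes lay on X. That chromosome held a far smaller share of all tested genes, 383 of 11604, and the excess was not tested. The reverse, silence in every CTRL library, held for 1 gene, Gm5640, which is named after its values were seen. In A375 it held for 0 genes in either direction, a count read directly with no test. The set silent in sg1 was defined after the data had been seen. With at most 10 counts allowed it held 46 genes, and with a CTRL mean of at least 100 counts it held 14.

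Of 41 tested interferon-stimulated genes, whose products restrict viruses, 33 rose and 0 fell in B16-F10, and 34 rose adjusted over the list alone (median 1.83). Usp18, a protease that removes ISG15 and restrains interferon signalling, rose from 16.5 ± 3.03 to 176 ± 26.3 CPM (SD, n = 3; log2 change 3.41). Isg15, a ubiquitin-like modifier, rose from 15.95 ± 0.540 to 150 ± 21.3 CPM (3.23), and the helicase gene Ddx60 rose by 3.34. The list moved up by camera (adjusted p = 1.7e-39) and still did at adjusted p = 0.034 with an estimated correlation. The medians per sg1 library were 1.69, 1.71 and 1.96.

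Of 15 tested interferon-gamma response genes and T cell chemokines, 11 rose and 1 fell, or 11 and 2 adjusted over the list alone (median 1.96; camera adjusted p = 1.0e-09, and adjusted p = 0.034 with an estimated correlation). The guanylate-binding proteins Gbp3 (3.08) and Gbp2 (2.97), which act against intracellular pathogens, rose with Gbp5. The immunity-related GTPase genes Irgm2 (2.89), of this list, and Igtp (3.17), named from the interferon-stimulated list, also rose. Their annotated spans overlap on chromosome 11 (from 58199618 for Irgm2 and 58199556 for Igtp), so their counts need not be independent. Of 19 tested genes of cytosolic nucleic acid sensing, 12 rose and 2 fell, also adjusted over the list alone (median 0.65; camera adjusted p = 3.3e-07, and adjusted p = 0.034 with an estimated correlation). The RNA sensors Ifih1, which encodes MDA5, and Ddx58, which encodes RIG-I, rose by 2.85 and 2.82, Ddx58 from 88.2 ± 2.83 to 624 ± 13.3 CPM (SD, n = 3). Trim25 (2.19), a ubiquitin ligase that acts on RIG-I, rose as well. For both lists the medians of the 3 sg1 libraries were all above 0, at 1.40, 1.75 and 2.0 and at 0.48, 0.64 and 0.82.

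Of 18 tested genes of MHC class I antigen presentation, 11 rose and 2 fell, also adjusted over the list alone (median 0.70; camera adjusted p = 1.4e-04). The list did not pass at adjusted p = 0.14 with an estimated correlation. B2m, the light chain of class I molecules, rose from 274 ± 13.4 to 1214 ± 152 CPM (SD, n = 3; 2.15). H2-T23 (2.94), a non-classical class I gene, and Tapbp (1.93), which loads peptides, rose, and H2-M3 (-2.05), another non-classical class I gene, fell. Of 8 tested interferon and receptor genes, 1 rose and 3 fell, also adjusted over the list alone (camera adjusted p = 0.88). Jak1, a kinase of the receptors, rose by 0.44. Ifnlr1 (-1.82), Il10rb (-0.38) and Ifnar1 (-0.35), receptor genes, fell, calls lost without CTRL replicate 3, CTRL replicate 2 and CTRL replicate 1 in turn (edgeR adjusted p = 0.056, 0.051 and 0.052). With chromosome medians removed Il10rb was at -0.10 (edgeR adjusted p = 0.36) and Ifnar1 at -0.07 (0.49). Over all alternatives the adjusted p ran from 5.0e-13 to 0.084 for Ifnlr1, from 1.7e-07 to 1 for Il10rb and from 5.5e-06 to 1 for Ifnar1. The list's median was 0.05, and -0.06 without sg1 replicate 3, and its camera direction down. Of 11 tested immune checkpoint and ligand genes, 3 rose and 2 fell, also adjusted over the list alone (camera adjusted p = 0.63, direction up with a median of -0.08). Leaving out 1 library moved this median, which was -0.28 without sg1 replicate 3, 0.05 without sg1 replicate 2, and -0.03 without sg1 replicate 1, CTRL replicate 1 or CTRL replicate 2. Cd274, which encodes PD-L1, rose by 1.94 from 14.0 ± 0.545 to 53.9 ± 24.2 CPM (SD, n = 3), Lgals9, which encodes galectin-9, rose by 1.55, and Ulbp1, a ligand of an activating receptor of natural killer cells, fell by 2.16. With a library left out the change of Ulbp1 ran from -2.82 to -1.86.

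Of 25 tested G1/S genes, 0 rose and 21 fell, also adjusted over the list alone (median -0.86; camera adjusted p = 7.0e-08, and adjusted p = 0.49 with an estimated correlation). Of 25 tested G2/M genes, 0 rose and 21 fell, or 22 adjusted over the list alone (median -0.64; camera adjusted p = 4.1e-06, and adjusted p = 0.60 with an estimated correlation). The replication genes Gins2 (-1.58), Cdt1 (-1.35) and Tk1 (-1.34) and the transcription factor gene E2f2 (-1.30) fell, as did the mitotic genes Ccnb2 (-1.58), Aurkb (-1.44), Top2a (-1.14) and Ube2c (-1.13). These genes moved with the difference between sg1 libraries, with medians of -0.68, -0.73 and -1.21 for G1/S and -0.44, -0.49 and -1.23 for G2/M in replicates 1 to 3.

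Of 24 tested genes of the integrated stress response and unfolded protein response, 2 rose and 14 fell, or 2 and 15 adjusted over the list alone (median -0.92; camera adjusted p = 0.0037, and adjusted p = 0.49 with an estimated correlation). The members with the largest falls were the cystine transporter gene Slc7a11 (-2.67, and -3.84 without sg1 replicate 3), the serine synthesis gene Phgdh (-1.80) and the mitochondrial folate gene Mthfd2 (-1.80), which supply amino acids and carbon units. Of 24 tested cholesterol synthesis genes, 0 rose and 15 fell, also adjusted over the list alone (median -0.49; camera adjusted p = 9.1e-04, and adjusted p = 0.49 with an estimated correlation). Among them was Insig1 (-1.03), a sterol sensor. Of 22 tested genes of hypoxia and glycolysis, 0 rose and 13 fell, also adjusted over the list alone (median -0.61; camera adjusted p = 0.0022, and adjusted p = 0.49 with an estimated correlation). Aldoc (-3.17), an aldolase, Slc16a3 (-2.65), a lactate exporter, and Slc2a1 (-1.10), a glucose transporter, fell. In sg1 replicates 1 to 3 the medians were -1.01, -1.01 and -0.59 for the stress response list and -0.89, -0.91 and -0.41 for hypoxia and glycolysis, so replicate 3 was nearest to CTRL in both.

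Of 19 tested genes of extracellular matrix and TGF-beta, 2 rose and 5 fell, or 1 and 5 adjusted over the list alone (median -0.48, unchanged with Col6a3 at its bound; camera adjusted p = 0.020, and adjusted p = 0.41 with an estimated correlation). Tgfb1 (-4.93, and -6.07 without sg1 replicate 3), a cytokine with 2, 1 and 8 counts in sg1, Mmp2 (-1.90), a matrix protease, and Col4a1 (-1.27), a basement membrane collagen, fell. Without CTRL replicate 3 the list's call was lost (camera adjusted p = 0.051, median -0.47, with a range of adjusted p over its alternatives from 7.0e-04 to 0.41), and without sg1 replicate 3 the median was -0.32. Of 18 tested genes of melanocyte differentiation and pigment, 8 rose and 4 fell, also adjusted over the list alone (median 0.45; camera adjusted p = 0.22). Sox10 (1.28) and Pax3 (1.25), transcription factor genes of the melanocyte lineage, rose with Gpnmb (0.98), a melanosome protein gene, and the channel gene Trpm1 (-1.01) fell. Their list median was 0.53, 0.53 and -0.01 in sg1 replicates 1 to 3, and it was 0.26 without sg1 replicate 1. Without sg1 replicate 3 the list passed (camera adjusted p = 0.0029, median 0.44, the lowest over its alternatives, the highest being 0.86).

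Of 10 tested NF-kB targets and inflammatory cytokines, 5 rose and 3 fell, also adjusted over the list alone (median 0.55; camera adjusted p = 0.22). Relb (2.60) and Nfkb2 (2.46), subunits of the non-canonical pathway, and Tnfaip3 (2.39), an inhibitor of NF-kB, rose, and Birc3 went from 60 counts in CTRL to 3 in sg1 (ratio 19.5, 95% counting interval 6.35 to 97.1). The list passed without sg1 replicate 3 (camera adjusted p = 0.017, median 1.14, the lowest over its alternatives, the highest being 0.57), and its median was 0.92 without CTRL replicate 3. Of 22 tested p53 targets, 7 rose and 5 fell, also adjusted over the list alone (median 0.13, and -0.04 without sg1 replicate 3; camera adjusted p = 0.34), with Btg2 (1.79) and Trp53inp1 (1.53), both linked to arrest of growth, higher and Fdxr (-1.40), a mitochondrial reductase, lower.

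Of the 27 lists 25 could be tested in B16-F10. By camera 11 passed, 3 of these with an estimated correlation, and by fry, which asks only whether a list moved on balance in 1 direction, 13 passed. For each list named above that passed by camera, the p with an estimated correlation was the highest over all alternatives. The sg1 libraries were not alike. In sg1 replicates 1 and 2 the variance over genes was 1.87 times that of counting alone, but 65.1 and 65.4 times between each of them and replicate 3, against 1.99 to 3.78 within CTRL. Genes and lists that passed only without sg1 replicate 3 thus rest on a small spread that may be technical, and are no stronger evidence. The changes of replicates 1 and 2 correlated at 0.97 with each other across genes and at 0.78 with those of replicate 3, genes not being independent replicates. Mitochondrially encoded genes took 2.79%, 2.69% and 2.67% of counts in CTRL and 1.65%, 1.57% and 3.15% in sg1 replicates 1 to 3, with means of 2.71 ± 0.0666% and 2.13 ± 0.887% (SD, n = 3; exact permutation p = 0.4).

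**Figure D1:**
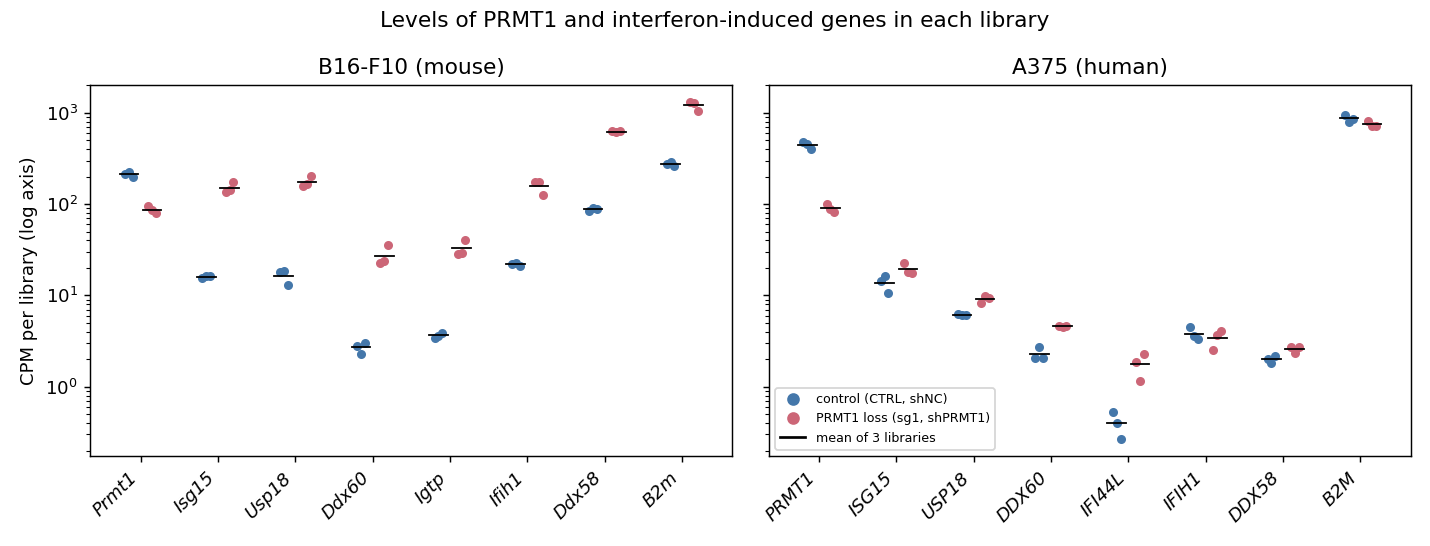
CPM (log axis) of PRMT1 and of interferon-induced or related genes in each library of B16-F10 (left) and A375 (right), with controls in blue, PRMT1 loss in red and a bar at the mean of 3 libraries. Isg15 went from 15.95 to 150 CPM in B16-F10, where PRMT1 fell to 86.7 CPM, and in A375 PRMT1 fell to 90.4 CPM.

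Next, whether whole chromosomes moved in B16-F10 was examined, a test chosen after the data had been seen. The genes of chromosome 18 were higher in sg1 (302 genes, median log2 change 0.39), and those of chromosome 9 (653 genes, median -0.33) and chromosome 16 (359 genes, median -0.27) were lower. In sg1 replicates 1 to 3 the medians were 0.30, 0.29 and 0.54 for chromosome 18, -0.34, -0.35 and -0.35 for chromosome 9 and -0.28, -0.27 and -0.30 for chromosome 16. On chromosome 9, 26.8% of genes had a change above 0, on chromosome 16 27.6% and on chromosome 18 74.5%. Carm1, Dnmt1, Fam81a and Tex12 lie on chromosome 9. In A375 the medians ran from -0.14 on chromosome 19 to 0.12 on chromosome 13. With each chromosome's median removed, 6133 genes of B16-F10 passed, and 5542 of the 6247 calls were kept with their direction.

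**Figure D2:**
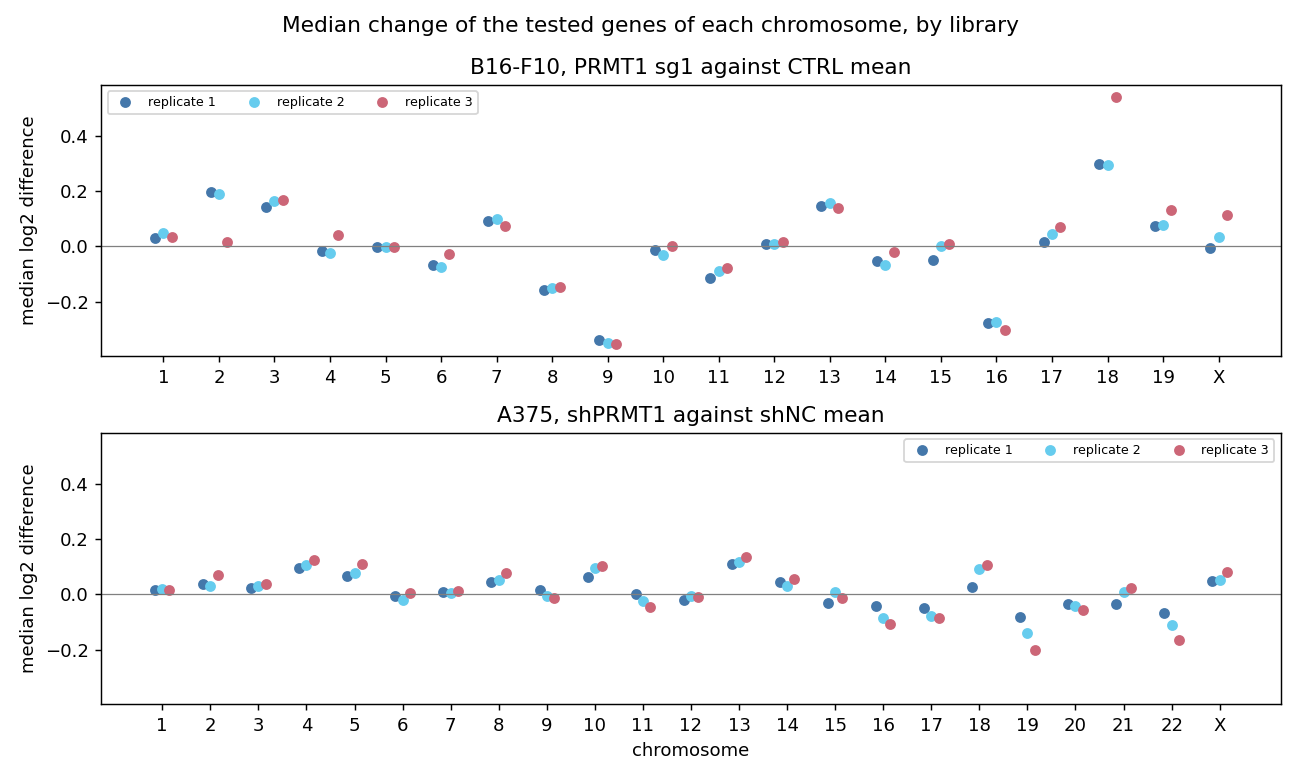
Median log2 difference of the tested genes of each chromosome between a PRMT1 loss library and the mean of the controls, with a point for each replicate of B16-F10 sg1 (top) and A375 shPRMT1 (bottom). Chromosomes 9 and 16 lie below 0 and chromosome 18 above 0 in all 3 sg1 libraries.

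To ask which genes changed after knockdown in the human line, shPRMT1 and shNC libraries of A375 were compared. PRMT1 (hg38, chromosome 19, 49675786 to 49689029) was read at 477, 460 and 403 CPM in the shNC libraries and at 101, 89.0 and 81.1 CPM in the shPRMT1 libraries. It fell from 447 ± 38.5 to 90.4 ± 10.1 CPM (SD, n = 3), a log2 change of -2.31 with a standard error of 0.0825 (edgeR adjusted p = 1.6e-17). Of 26 gene lists that could be tested 3 passed by camera, those of G1/S, of cholesterol synthesis and of interferon-stimulated genes, and 0 passed with an estimated correlation (adjusted p = 0.24, adjusted p = 0.24 and adjusted p = 0.32). For G1/S the estimated correlation was -0.016, below the preset 0.01, so a larger correlation is not why its call was lost. Of 13044 genes tested, 2696 rose and 2727 fell, together 41.6%, of which 191 rose and 228 fell by at least 2-fold, and the median absolute log2 change of the changed genes was 0.39. Ranges of the groups did not overlap for 5048 of the changed genes and for 49.4% of tested genes, against 10% by chance. Against a minimum change of 1.5-fold 278 genes passed, and with TPM of transcripts assembled in each library apart 1 gene passed. That gene was higher, and 0 calls of the main test were kept with their direction, so PRMT1 itself was missed there.

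Among PRMT family members CARM1 rose by 0.25 (edgeR adjusted p = 0.0060). PRMT6 differed by 0.22 (edgeR adjusted p = 0.019), a call lost without shNC replicate 3 (0.067), shPRMT1 replicate 2 (0.064) or shPRMT1 replicate 3 (0.073), and PRMT7 by -0.26 (edgeR adjusted p = 0.012), lost without shNC replicate 3 (0.11). Over all alternatives these adjusted p ran from 0.0040 to 1 for PRMT6 and from 8.4e-04 to 1 for PRMT7. In the list 2 of 8 tested members rose and 2 fell, or 2 and 3 adjusted over the list alone (camera adjusted p = 0.11, direction down with a median of 0.07, and 0.02 to 0.11 with a library left out). The largest rise was that of VSTM2L (hg38, chromosome 20, 37903111 to 37945350), from 0.146 ± 0.135 to 2.03 ± 0.751 CPM (SD, n = 3; log2 change 3.69). The cytochrome P450 gene CYP4F11 (2.89), the tyrosine kinase gene BMX (2.87), the potassium channel gene KCND3 (2.86), the engulfment receptor gene MEGF10 (2.81), the transglutaminase gene TGM4 (2.64), the serpin gene SERPINB7 (2.50) and the galactosyltransferase gene B3GALT2 (2.45) also rose. The largest falls were those of CORO6 (-2.84), a coronin, SALL4 (-2.72), a zinc finger transcription factor, PRMT1 itself, MERTK (-2.26), a receptor tyrosine kinase, the transporter gene ABCC6 (-2.18), the homeobox gene PITX1 (-2.16), the transcription factor gene NHLH1 (-2.14) and the protease gene PRSS53 (-2.13).

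Of 41 tested interferon-stimulated genes in A375, 18 rose and 1 fell, also adjusted over the list alone (median 0.25; camera adjusted p = 0.0092). The list did not pass at adjusted p = 0.32 with an estimated correlation. IFI44L rose from 0.399 ± 0.132 to 1.76 ± 0.561 CPM (SD, n = 3; log2 change 2.14), DDX60 by 1.01 and SAMD9L by 0.68, and the exonuclease gene ISG20 fell by 0.65. Of 13 tested interferon-gamma response genes and T cell chemokines, 2 rose and 2 fell, also adjusted over the list alone (camera adjusted p = 0.97, direction down with a median of 0.04, and -0.09 to 0.10 with a library left out), with GBP2 at 0.48 and SOCS3, an inhibitor of cytokine signalling, at -0.57. Of 20 tested genes of nucleic acid sensing, 5 rose and 4 fell, also adjusted over the list alone (camera adjusted p = 0.92), among them TLR3 (0.70), SAMHD1 (0.64) and RNASEH2C (-0.77). Of 21 tested genes of MHC class I presentation, 5 rose and 3 fell, also adjusted over the list alone (camera adjusted p = 0.58), with HLA-F (0.65) and the chaperone gene CANX (0.56) higher and the immunoproteasome gene PSMB9 (-0.41) lower. Of 7 tested interferon and receptor genes, 2 rose and 2 fell, also adjusted over the list alone (camera adjusted p = 0.91, direction down with a median of 0.0052, and -0.27 to -0.0030 with a library left out), with TYK2, a kinase of the receptors, at -0.51. Of 16 tested immune checkpoint and ligand genes, 3 rose and 4 fell, also adjusted over the list alone (camera adjusted p = 0.97, direction up with a median of -0.02, and -0.02 to 0.09 with a library left out), with CEACAM1 at -1.76. The change of CEACAM1 ran from -2.57 to -1.43 with a library left out.

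Of 25 tested G1/S genes, 2 rose and 15 fell, also adjusted over the list alone (median -0.23; camera adjusted p = 0.0010, and adjusted p = 0.24 with an estimated correlation). E2F2 (-0.75), E2F1 (-0.71), CDT1 (-0.61) and CCND1 (-0.59), which promote entry into S phase, fell. Of 24 tested G2/M genes, 1 rose and 7 fell, also adjusted over the list alone (median -0.11; camera adjusted p = 0.091), with the mitotic kinase genes AURKB (-0.72) and PLK1 (-0.70) lower and AURKA (0.92) higher. Without shNC replicate 1 this list passed (camera adjusted p = 0.045, with a range over its alternatives from 0.0013 to 0.32). Of 23 tested cholesterol synthesis genes, 1 rose and 10 fell, or 1 and 11 adjusted over the list alone (median -0.15, and -0.23 without shPRMT1 replicate 1; camera adjusted p = 0.0010, and adjusted p = 0.24 with an estimated correlation). DHCR7 (-1.60) and MVK (-0.73), enzymes of the pathway, and INSIG1 (-1.48), a sterol sensor, fell.

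Of 14 tested genes of melanocyte differentiation and pigment, 1 rose and 5 fell, or 1 and 7 adjusted over the list alone (median -0.20; camera adjusted p = 0.11), with DCT (-1.68), a melanin enzyme, and MC1R (-0.89), the melanocortin receptor, lower. Of 24 tested genes of hypoxia and glycolysis, 6 rose and 5 fell, also adjusted over the list alone (camera adjusted p = 0.93), with GAPDH (-0.75) and SLC2A3 (-0.65) lower and PFKFB3 (0.55) higher. Of 25 tested genes of the integrated stress response and unfolded protein response, 6 rose and 6 fell, or 8 and 7 adjusted over the list alone (camera adjusted p = 0.93, direction up with a median of -0.02, and -0.08 to 0.02 with a library left out), with XBP1 (0.66), a regulator of the unfolded protein response, higher and SESN2 (-0.65) lower. Of 25 tested genes of extracellular matrix and TGF-beta, 10 rose and 4 fell, also adjusted over the list alone (camera adjusted p = 0.33), with COL4A2 at -0.93. Of 22 tested NF-kB targets, 1 rose and 6 fell, also adjusted over the list alone (camera adjusted p = 0.35), with the chemokine gene CXCL1 at -1.40, and of 25 p53 targets 2 rose and 9 fell, also adjusted over the list alone (camera adjusted p = 0.11), with DDB2, a DNA repair gene, at -0.55. In A375, 26 of the 27 lists could be tested, of which 3 passed by camera, 0 by camera with an estimated correlation (2 at an unadjusted p under 0.05) and 11 by fry. Mitochondrially encoded genes took 3.75 ± 0.0898% of counts in shNC and 4.23 ± 0.114% in shPRMT1 (SD, n = 3; exact permutation p = 0.1). For each of the 3 that passed, the p with an estimated correlation was the highest over all alternatives.

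**Figure D3:**
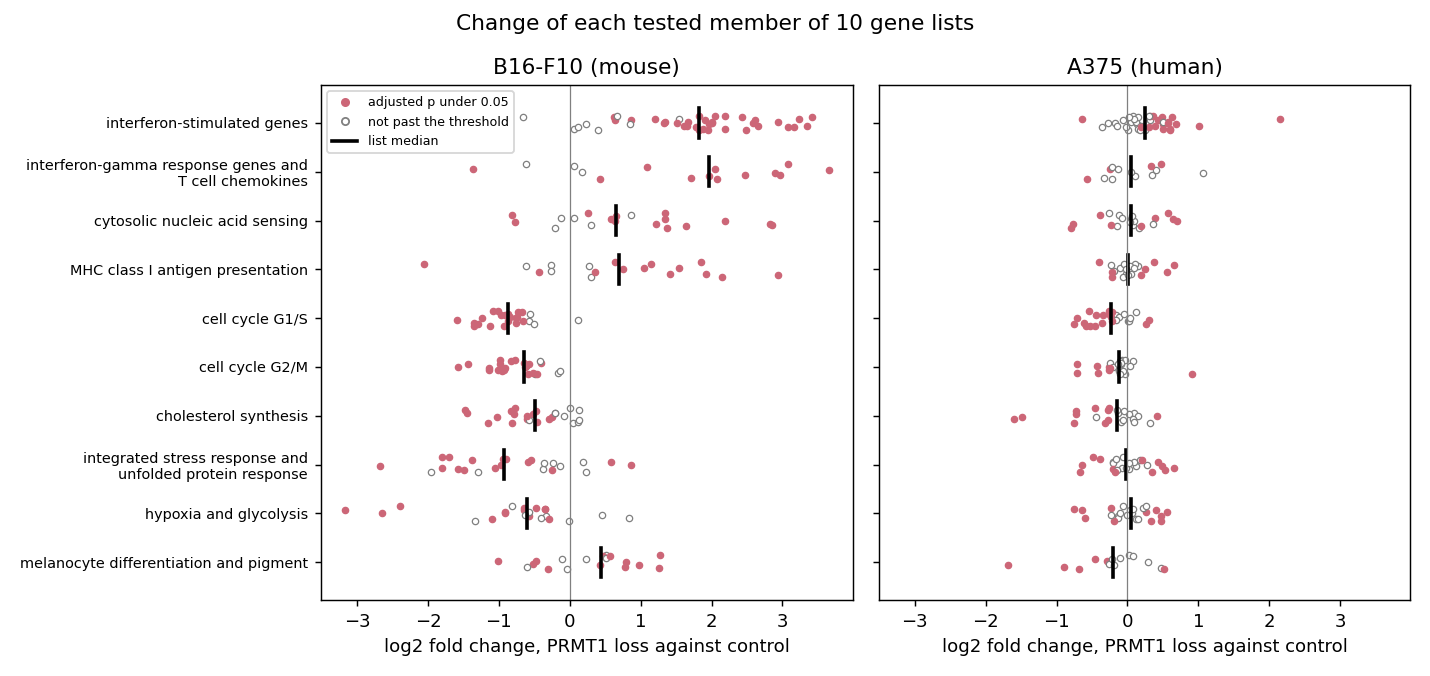
Log2 change of each tested member of 10 gene lists in B16-F10 (left) and A375 (right), filled where the member passed the edgeR test, with a bar at the list's median. The median of interferon-stimulated genes was 1.83 in B16-F10 and 0.25 in A375.

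Finally, the changes of both lines were compared on 9800 genes that share a symbol and were tested in both, by an interaction term. Interferon-stimulated genes rose more in B16-F10 than in A375, in 23 of 30 paired members past the threshold and in 0 the other way (median difference of the log2 changes 1.53; camera adjusted p = 6.4e-18, and adjusted p = 0.0063 with an estimated correlation). Genes of nucleic acid sensing also differed (17 paired, 12 more positive in B16-F10 and 2 more negative, median 0.79; camera adjusted p = 1.0e-04, and adjusted p = 0.016 with an estimated correlation). In all, the change of 4932 genes differed between the lines (50.3%), 2487 being more positive in B16-F10 and 2445 more negative. Line, species, and the use of a guide or a hairpin change together here, and Prmt1 itself was at 213 CPM in CTRL and PRMT1 at 447 CPM in shNC.

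Of 23 lists tested for a difference 9 passed by camera. The remaining 7 lost their call with an estimated correlation. G1/S (median difference -0.56; camera adjusted p = 7.6e-04, and adjusted p = 0.61 with an estimated correlation) and G2/M (-0.67; camera adjusted p = 7.6e-04, and adjusted p = 0.69 with an estimated correlation) fell further in B16-F10. The stress response list (-0.70; camera adjusted p = 0.0030, and adjusted p = 0.39 with an estimated correlation), hypoxia and glycolysis (-0.58; camera adjusted p = 0.0030, and adjusted p = 0.39 with an estimated correlation) and extracellular matrix (-0.26; camera adjusted p = 0.0030, and adjusted p = 0.24 with an estimated correlation) were lower in B16-F10. MHC class I presentation (0.28; camera adjusted p = 0.012, and adjusted p = 0.39 with an estimated correlation) and melanocyte genes (0.58; camera adjusted p = 0.0065, and adjusted p = 0.55 with an estimated correlation) were higher. These tests cover only members paired by symbol, 13 for MHC class I presentation, against 18 tested in B16-F10 and 21 in A375. For interferon-gamma response genes 7 members were paired, against 15 tested in B16-F10 and 13 in A375. Of the 7, 4 were more positive in B16-F10 and 1 more negative (median difference 0.65), and the list did not pass (camera adjusted p = 0.052). The unpaired members were not compared. For cholesterol synthesis (camera adjusted p = 0.32) a difference was not shown.

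The largest single differences were those of genes that fell almost to 0 counts in B16-F10. OSMR rose in A375 by 0.34 from 59.5 ± 3.66 to 75.3 ± 1.60 CPM (SD, n = 3; edgeR adjusted p of the difference 6.7e-09), and FOXR2 was at 10.6 ± 0.992 and 13.9 ± 2.50 CPM (difference 2.9e-10). The rise of FOXR2 in A375 (0.40, edgeR adjusted p = 0.017) was lost without shNC replicate 1 (0.077), shNC replicate 2 (0.064), shPRMT1 replicate 2 (0.054) or shPRMT1 replicate 3 (0.13). PTGFRN, a membrane protein gene, was at 132 ± 9.32 and 133 ± 5.39 CPM in A375 (SD, n = 3; edgeR adjusted p of the difference 1.1e-09), where in B16-F10 Ptgfrn went from 557 counts to 1 (ratio 542, 95% counting interval 97.0 to 21464). CNKSR2, a scaffold of kinase signalling, differed by 0.18 in A375 (edgeR adjusted p = 0.41) and was at least 58.8-fold lower in B16-F10. COL6A3 (-0.59) and FAM81A (-0.57) did not pass in A375 (edgeR adjusted p = 0.076 and 0.072), though COL6A3 did without shPRMT1 replicate 2 (-1.01, 0.0088) and FAM81A without shNC replicate 3 (0.043) or shPRMT1 replicate 3 (0.028).

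Some genes changed in the same direction in both lines. MERTK fell by 4.003 in B16-F10 and by 2.26 in A375 on the log2 scale, from 134 ± 7.05 to 8.36 ± 0.588 CPM and from 1.62 ± 0.347 to 0.343 ± 0.162 CPM (SD, n = 3). RASGRP3 (-1.40 and -1.86), a Ras activator, NREP (-2.15 and -1.37) and XKR5 (-1.66 and -1.37) fell, and PRICKLE1 (2.02 and 1.36), a gene of planar cell polarity, and GAB3 (1.33 and 1.60), a signalling adaptor, rose. TAS1R3 (1.88 and 1.58), a taste receptor gene, lost its A375 call without shNC replicate 2 (edgeR adjusted p = 0.059) or shPRMT1 replicate 2 (0.062), and SLC18A1 (2.06 and 1.31), a monoamine transporter gene, without shNC replicate 2 (0.055). Over all alternatives these ran from 0.0060 to 0.23 and from 0.0075 to 0.30. Most of these genes were low in A375, where fold changes rest on few counts. Over both A375 groups the mean was 1.36 CPM for RASGRP3, 1.57 for XKR5, 1.20 for GAB3, 0.68 for TAS1R3 and 0.91 for SLC18A1. NREP was at 10.2 CPM and PRICKLE1 at 5.58. Across the 9800 genes 668 were higher in both lines (581.2 for independent lists; odds ratio 1.29, Fisher's exact p = 2.6e-06) and 692 lower in both (586.8; odds ratio 1.36, Fisher's exact p = 1.4e-08). Fewer than independence gives were higher in B16-F10 and lower in A375 (452 against 575.8; odds ratio 0.67, Fisher's exact p = 4.2e-12), and 557 were lower in B16-F10 and higher in A375 (592.3; odds ratio 0.90, Fisher's exact p = 0.056). So 1360 genes changed in the same direction and 1009 in opposite directions, and the log2 changes correlated across genes at r = 0.04 and rho = 0.09, genes not being independent replicates.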

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

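The tests of list differences between the lines, and the bounds and ratios of genes with few counts, were chosen only after the results were seen. The change of 4932 of 9800 paired genes differed between B16-F10 and A375 by the interaction test of edgeR. Among 100 of the 200 splits of the libraries within both lines, 2 gave as many genes, the real one included. The other, with 5412 genes, was the split that exchanges the control and loss groups of 1 line and keeps them apart, and the next gave 3451. Splits that mix control and loss libraries put the change itself into the spread within groups, so these counts are not taken to exclude chance. For the 1360 genes changed in the same direction in both lines these splits are no test, since every split within a line other than the real one called 0 genes.

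Further results stood out because the changes of lists differed between the lines by camera. With an estimated correlation the calls of interferon-stimulated genes (adjusted p = 0.0063) and nucleic acid sensing (adjusted p = 0.016) were kept, and those of the remaining 7 lists were lost (adjusted p = 0.24 for extracellular matrix and TGF-beta, adjusted p = 0.39 for MHC class I, the stress response and hypoxia and glycolysis, adjusted p = 0.55 for melanocyte genes, adjusted p = 0.61 for G1/S and adjusted p = 0.69 for G2/M). The median differences of the log2 changes, B16-F10 minus A375, were 1.53 for interferon-stimulated genes, 0.79 for nucleic acid sensing, 0.28 for MHC class I antigen presentation, 0.58 for melanocyte differentiation and pigment, -0.56 for G1/S, -0.67 for G2/M, -0.70 for the integrated stress response and unfolded protein response, -0.58 for hypoxia and glycolysis and -0.26 for extracellular matrix and TGF-beta. Single genes stood out by the interaction test of edgeR. From ratios of counts the difference of the log2 changes was -11.09 for FOXR2, -9.16 for FAM81A and -9.09 for PTGFRN. With sg1 at the floor of 3 counts over the group the difference was at most -7.14 for OSMR, -6.06 for CNKSR2 and -5.95 for COL6A3. Line, species and the way PRMT1 was lowered differ together, and these were not tested apart.

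For the counts within a line, the 10 splits of 6 libraries are too few for a share under 0.05. The real split gave 6247 genes and 11 lists in B16-F10, with 0 genes and 9 lists in the highest other split. In A375 it gave 5423 genes and 3 lists, with 0 genes and 2 lists in the highest other.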

How the results depend on the processing

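Chosen only after the results were seen were the tests with sg1 replicate 3 alone, with replicates 1 and 2 summed, with chromosome medians removed and the assignment of assembled transcripts to genes. Prmt1 stayed lower in both lines under the other scalings, the replicate block, DESeq2, limma-voom and each library left out, and in B16-F10 with sg1 replicate 3 alone and with replicates 1 and 2 summed (-1.42 to -1.25 in B16-F10, -2.39 to -2.23 in A375). Its change was not read out under the remaining alternatives. With TPM of assembled transcripts, though, the 1 gene that passed in A375 was higher and was not a call of the main test. PRMT1 thus did not pass as lower there, so that alternative missed the targeted gene itself. The count of 6247 genes in B16-F10 lay between 5584 with the replicate block and 6473 with DESeq2 under scaling, filter, block and test alternatives, was 7870 with sg1 replicate 3 alone, and ran from 4793 to 8962 with a library left out, the highest without sg1 replicate 3. It was 1638 against a minimum change of 1.5-fold, a stricter test, and 3223 with replicates 1 and 2 summed, which leaves fewer samples and in which 27 named genes no longer passed, Slc7a11 among them (edgeR adjusted p = 0.066). In A375 the count of 5423 ran from 4306 to 5322 with a library left out, was 4747 with DESeq2 and 6388 with the replicate block, and was 278 against a minimum change of 1.5-fold. Replicate numbers were not taken as pairs, since no source states that libraries of a number shared a day. Controls correlated with the loss library of their own number at -0.03, -0.03 and -0.04 in B16-F10 and at 0.08, 0.02 and 0.12 in A375. In A375 controls 1 and 3, but not 2, correlated best with their own number, and the second principal component went down with the number in both groups (10.96, 0.77 and -13.57 in shNC, 15.40, -2.11 and -11.45 in shPRMT1), a hint from the data that the libraries share something by number there. The correlation of a library's difference from its group mean with exon length also rose with the number in both groups. It was -0.31, 0.01 and 0.30 in shNC and -0.25, 0.03 and 0.23 in shPRMT1. The main A375 fit does not model this trend, which stays in its spread within groups. With TPM of transcripts assembled in each library apart, 1 gene passed in A375 by limma. Among the named genes that had passed in the main test, 94 kept their sign there but no longer passed. Another 12 took the other sign without passing: CARM1 -0.0031, CIITA 0.12, HLA-F -0.12, TYK2 0.40, RAB27A -0.088, CCND1 0.086, PLK1 0.36, CD47 -0.17, SFPQ -0.23, MT-ND2 -3.84, MT-ND5 -4.65 and LUM 0.44, and the cause was not tested. Turns of sign in named genes that had not passed, and in genes not named, were not counted. Lists past camera numbered 9 to 14 of 25 in B16-F10 and 3 to 4 of 26 in A375 with a library left out. In B16-F10 they numbered 11 with chromosome medians removed, where extracellular matrix (camera adjusted p = 0.17) and fibroblast markers (0.051) lost their calls and ribosomal proteins (0.027) and mitochondrially encoded genes (0.030) passed. They numbered 9 with sg1 replicate 3 alone, where hypoxia and glycolysis (camera adjusted p = 0.068), extracellular matrix (0.053) and fibroblast markers (0.10) lost their calls and RNA-binding proteins (0.0055) passed. With an estimated correlation 3 passed in B16-F10 and 0 in A375, where interferon-stimulated genes (0.25) did not (camera adjusted p = 0.32, the highest over the alternatives, the lowest being 0.0011). In A375, 6 passed without a filter, 6 with the replicate block and 11 by fry, and the cause was not tested beyond the questions these tests ask. The median of interferon-stimulated genes ran from 1.70 to 1.96 in B16-F10, from 0.19 to 0.31 in A375 and from 1.43 to 1.57 for the difference. The count of genes whose change differs ran from 4366 to 6318 with a library left out (the highest without sg1 replicate 3) and was 4820 with the replicate block. The overlap of genes lower in both lines by at least 2-fold, with fewer genes, had an odds ratio of 1.83 (Fisher's exact p = 0.054). Of the repeats of named genes, 1988 in B16-F10 and 1636 in A375 kept their side of the threshold, 131 and 232 no longer passed and 1 and 8 newly passed. A change of sign was counted only where the main test or the repeat passed, and 0 and 12 repeats had it. Genes that passed in neither could turn sign and still count as kept. With a library left out, Fcer1g ran from -0.40 to 0.63 in B16-F10 and PECAM1 from -0.39 to 0.21 in A375. In the simulated data changes of 1.5-fold were recovered least often, and the part of depth in this was not tested. Transcripts and isoform shares were not run.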

Other observations

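The tests of CTRL RNA in sg1 replicate 3, of a length or level trend, of chromosome medians without strongly changed genes and of windows along chromosomes were chosen only after the results were seen. Genes of chromatin and of RNA-binding proteins changed in both directions in B16-F10. Of 21 tested genes of DNA methylation and retroelement silencing, 5 rose and 10 fell, also adjusted over the list alone (camera adjusted p = 0.27), with Tet1 (-1.59) and the maintenance methyltransferase gene Dnmt1 (-1.34) lower and Tet2 (1.11) higher. Of 20 tested enzymes and readers of H3K27 acetylation, 5 rose and 4 fell, also adjusted over the list alone (camera adjusted p = 0.84), with the acetyltransferase gene Ep300 (0.90) and the deacetylase gene Sirt1 (0.86) higher. Of 26 tested genes of RNA-binding proteins with arginine-glycine repeats, substrates of PRMT1 among them, 1 rose and 12 fell, or 1 and 11 adjusted over the list alone (camera adjusted p = 0.24), with Taf15 (-0.84) and G3bp1 (-0.76) lower. Of 44 tested ribosomal protein genes 1 rose and 9 fell, or 1 and 8 adjusted over the list alone (camera adjusted p = 0.17), and the list passed without sg1 replicate 3 (median -0.28, camera adjusted p = 0.0016, the lowest over its alternatives, the highest being 0.88). Of 13 tested mitochondrially encoded genes 0 rose and 5 fell, or 0 and 1 adjusted over the list alone (camera adjusted p = 0.18), with medians of -0.77, -0.89 and -0.14 in sg1 replicates 1 to 3, and the list passed without replicate 3 (median -0.84, camera adjusted p = 1.7e-05, the lowest over its alternatives, the highest being 0.97). Of 16 tested genes of dedifferentiated melanoma 3 rose and 4 fell, also adjusted over the list alone (camera adjusted p = 0.88, direction up with a median of -0.18, which was 0.05 without sg1 replicate 3, -0.29 without sg1 replicate 1, -0.30 without CTRL replicate 2 and -0.10 without CTRL replicate 3), with Jun (2.03) higher and Thbs1 (-1.58) lower. Of 15 tested genes of MAPK output 3 rose and 3 fell, or 3 and 0 adjusted over the list alone (camera adjusted p = 0.66, direction up with a median of -0.37, which ran from -1.06 without sg1 replicate 3 to -0.14 with a library left out), with Phlda1 (1.53) higher and list medians of -0.71, -0.86 and 0.31 in sg1 replicates 1 to 3.

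In A375, 5 of 22 tested genes of DNA methylation and silencing rose and 7 fell (camera adjusted p = 0.97), with TET3 (0.57) higher and SUV39H1 (-0.55) lower, and 4 of 21 tested genes of H3K27 acetylation rose and 5 fell (camera adjusted p = 0.97), both also adjusted over the list alone. Of 26 tested genes of RNA-binding proteins 7 rose and 3 fell, or 7 and 2 adjusted over the list alone (camera adjusted p = 0.57), with SRSF3 at 0.33. Of 45 tested ribosomal protein genes 2 rose and 14 fell, or 2 and 12 adjusted over the list alone (camera adjusted p = 0.17), and the list passed without shNC replicate 3 (camera adjusted p = 0.024) or shPRMT1 replicate 1 (0.0030), with a range over its alternatives from 0.0030 to 0.98. Their share of counts fell with the replicate number in both groups (11.9%, 10.9% and 10.3% in shNC, 10.8%, 9.89% and 9.39% in shPRMT1). Leaving out either library thus unbalances the groups. Of 13 tested mitochondrially encoded genes 6 rose and 0 fell, or 7 and 0 adjusted over the list alone (median 0.24; camera adjusted p = 0.091), and the list passed without shPRMT1 replicate 3 (camera adjusted p = 0.016, with a range over its alternatives from 0.012 to 0.79). Of 21 tested genes of dedifferentiated melanoma 6 rose and 3 fell, also adjusted over the list alone (camera adjusted p = 0.17), with NUAK1 (0.88), INHBA (0.84) and the receptor gene AXL (0.44) higher. Of 20 tested genes of MAPK output 6 rose and 5 fell, also adjusted over the list alone (camera adjusted p = 0.97, direction down with a median of 0.04, and 0.02 to 0.06 with a library left out), with EPHA4 (1.11) higher and SPRY2 (-0.61), a feedback inhibitor, lower. Markers of other cells were few. In B16-F10 the leukocyte list had 2 tested members, of which 0 changed (camera adjusted p = 0.90, with 0 of 2 also past edgeR at an unadjusted p under 0.05), the endothelial list 1 (Vwf, from 3.0 ± 0.353 to 18.4 ± 6.16 CPM, SD, n = 3), the keratinocyte list 1 (Cdh1, -3.54) and the fibroblast list 3, of which 0 rose and 2 fell (Pdpn -2.28, Postn -1.36; camera adjusted p = 0.011, and adjusted p = 0.49 with an estimated correlation). That call was lost without CTRL replicate 1 (camera adjusted p = 0.15), CTRL replicate 2 (0.11), CTRL replicate 3 (0.21) or sg1 replicate 3 (0.061). In A375 the leukocyte list had 1 tested member (LYZ, 0.80), the endothelial list 4 with 0 changed (camera adjusted p = 0.91), the fibroblast list 4 with 0 higher and 2 lower (DCN -1.09; camera adjusted p = 0.33) and the keratinocyte list 4 with 2 higher and 0 lower (KRT14 0.73, KRT18 0.59; camera adjusted p = 0.11).

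Replicate 3 of sg1 stood apart from replicates 1 and 2. On the second principal component, with 14.0% of the variance against 80.7% on the first, it lay at -43.3, and replicates 1 and 2 at 15.9 and 15.6. A large share of CTRL RNA in the library is argued against, since 53 genes silent in replicates 1 and 2 sat in replicate 3 at a median of 0.0449 of the CTRL level (quartiles 0.0032 and 0.0941), although 90 of 635 genes lowered in replicates 1 and 2 were back at 80% of CTRL or more. A small share, near these ratios, is not excluded. A trend with gene length and level is argued against, since removing it left 95.6% of the SD of the difference (0.604, against 0.248 between replicates 1 and 2). The labels give no biological difference between these libraries, so no biological explanation was tested, and what set replicate 3 apart stays open.

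The genes of chromosomes 9, 16 and 18 were shifted as wholes in B16-F10 sg1. A few strongly changed genes cannot set a median over this many genes. Without genes of absolute log2 change over 1 the medians were -0.25, -0.24 and 0.30, but this test could hardly have failed and adds no support. Chance placement is argued against, since the SD of the chromosome medians (0.157, against 0.0690 in A375) had a rotation p of 2.0e-04, from 10000 rotations with 1 added to both counts, the highest SD among them being 0.158. A different DNA copy number of the compared cell populations stays open. All 17 windows of these chromosomes had the sign of their chromosome in all 3 sg1 libraries, 16 of them beyond 0.1, but they are cut from the genes for whose shift the chromosomes were picked, so this decides nothing. Elsewhere 32 of 121 windows also kept 1 sign beyond 0.1, among them the windows of chromosome 8 from 80 Mb (-0.40, -0.46 and -0.45 in sg1 replicates 1 to 3) and from 120 Mb (-0.55, -0.52 and -0.53). The series holds ChIP input libraries of B16-F10 CTRL and sg1, which could bear on DNA copy number, but they were not analysed here. An effect of PRMT1 loss on these chromosomes was not tested.

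In the A375 assemblies, transcripts antisense to genes of the count table took 38.3 ± 2.22% of TPM in shNC and 38.0 ± 1.38% in shPRMT1 (SD, n = 3; exact permutation p = 1). They may be copies of sense transcripts placed on the other strand by the assembly, since 93.0% of their introns had both ends at exon ends of the gene on the opposite strand, against 89.2% at annotated exon ends for sense transcripts. By library this share was 92.7% to 93.2%. It argues against antisense transcription for these spliced transcripts, which would not be expected to share both ends of most introns with the opposite gene. Transcripts without introns were not tested. Transcripts outside the genes of the table took 3.43 ± 0.124% in shNC and 3.08 ± 0.276% in shPRMT1 (SD, n = 3; exact permutation p = 0.1, the smallest this design allows).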
